A study of Homo sapiens with 2 samples.

How the data were processed

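Nuclei of untreated MCF7 cells were subjected to a nuclear run-on with Br-UTP, the labelled RNA was immunoprecipitated, and libraries were made from biological duplicates with a small RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie as a tool, without a version. The genome build, the annotation, the counting rule and the use of strand are not given in the sources used here. The deposited table holds 2 columns of FPKM, a unit that scales the reads of a gene by its length and by the size of its library, kept to 3 decimals. The lengths and read totals behind it are not given in the sources used here. Both columns have 1 and the same name, that of replicate 1 of the untreated cells. Each was taken as 1 measurement of the group without a replicate number, and the SD over them has n = 2. The columns are not copies of each other, since 2 of 11410 transcripts had equal values. Protocols speak of separate biological replicates, but the column names do not show which of them the second column holds.

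The title of the table points to a minimum of 20, whose quantity is not stated. It is not a minimum on FPKM in these 2 columns, since 6574 values in the first column and 6539 in the second were under 20. Gene presence is therefore relative to an unknown filter. Symbols were matched to a RefSeq gene table (GRCh38.p14) and a table of older symbols. Of 11410 transcripts 10229 had a current symbol, 915 an older symbol with 1 current name and 266 (2.33%) a symbol that was not matched. Of the 11069 with an annotated type, 10942 were protein-coding. Because no build is named, no coordinates or gene lengths were taken from the reference, which served for names, gene types and the order of neighbouring genes.

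Depth was examined through the steps between values, since under whole-read counting each value is a whole multiple of what 1 read is worth for that gene. Over trial ratios of this worth between the columns, the number of genes whose ratio fitted whole reads between 20 and 40, within rounding, was counted. Of 10099 genes above 5 FPKM in both columns, 2210 (21.9%) fitted at a ratio of 1.05, against a mean of 400 (3.96%) and a highest number of 1452 (14.4%) at other ratios. That highest number was met at a ratio of 0.785, which is 0.75 times the first. The ratio with the best fit puts the second column 4.63% deeper. Absolute read numbers need the gene lengths, so no count test and no counting interval was computed.

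Levels were the mean of log2(FPKM + 1) over the columns. Before the data were examined, 20 gene lists with 321 distinct genes were fixed, 4 of them cell type markers. For 16 lists with at least 3 listed members, the median level was set against 10000 random lists of the same size, and the median log2 ratio of the columns against 10000 random lists matched on level in 10 bins. A percentile is the share of random lists below the value. Markers listed and not listed were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 3 comparisons. There was 1 group, so no test between conditions was possible. Named genes followed a rule fixed beforehand. It took the 20 genes with the highest lower value, the 4 highest and the lowest listed member of each list, the 5 largest and 5 smallest ratios of the columns among genes above the median level, and every listed luminal and basal or mesenchymal marker. Absent markers, the mitochondrial and MTRNR2L genes outside this rule, and the genes of neighbouring runs and symbol families were chosen after their values were seen.

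Planned comparisons of level with gene length and with 5 Mb windows need lengths and positions of the build used, and were not run. In their place runs of 15 neighbouring listed genes were compared, an analysis chosen after seeing the data, for 11059 genes (96.9%) with a place in the reference order. Alternatives covered the pseudocount, the limit of fold difference, centring, filters on low genes, the mean in place of the median, and leaving out each column.

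Procedures were tested on simulated data over 11410 genes. Of 200 genes changed 4-fold between the columns, all drawn from above the table median, 199 exceeded the 2-fold limit. With none changed, 34 of all genes exceeded it. Recovery among lower genes was not simulated. Of 1000 random lists of 15 genes, 4.8% fell outside the central 95%, and 100% of such lists raised 4-fold lay above it. A simulated depth ratio of 1.1 was recovered as 1.10 over 2870 genes. The simulated reads per gene lay mostly between 20 and 40, the searched range, which the real columns need not share. A list of 15 genes lowered by 0.5 on the log2 scale between the columns was at percentile 0. The highest run found began 1 gene away from a run raised by 4 on the log2 scale. Levels were in random order there, so no real cluster of high genes competed with the raised run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used, with a fixed random seed.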

Results

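Nascent RNA was measured by global run-on sequencing (GRO-seq) in MCF7, an estrogen receptor-positive human breast cancer cell line, kept in serum-containing medium and not treated. In this assay isolated nuclei extend the RNA that engaged polymerases already carry, with a bromine-labelled nucleotide, and the labelled RNA is captured and sequenced. A value therefore follows transcribing polymerase on a gene, not the amount of mature RNA. The stated purpose was to measure transcription rates. The 2 libraries formed 1 group, so the comparisons were among genes and between the 2 columns of the table. The table listed 11410 transcripts with 11409 gene symbols in FPKM, fragments scaled by gene length and library size. Both columns carry the label of replicate 1, so they are called the first and the second column here. Whether the second column is the other biological replicate or a further measurement of the first stays open, and each SD below may therefore be technical. The column medians were 16.7 FPKM in both, and the sums were 394953 and 391941. The best fit to the steps between values put the depth of the second column 4.63% above that of the first, and the absolute depth of both is unknown.

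The 20 genes with the highest lower value held genes of the mitochondrial genome and copies of them, histone and keratin genes, and several transcripts with clone names. MT-ND4L, a subunit of respiratory complex I, had the highest mean of 10642 ± 5808 FPKM (SD, n = 2), and its columns were 2.26-fold apart. MT-CO2, MT-ATP6 and MT-CO1, subunits of cytochrome oxidase and ATP synthase, had means of 6208 ± 488, 4938 ± 768 and 4110 ± 74.4 FPKM. MTRNR2L8 and MTRNR2L1, nuclear genes that nearly copy a mitochondrial ribosomal RNA, had means of 8922 ± 2120 and 1805 ± 261 FPKM. Reads from such copies can be split or shared in the counting, so these levels are uncertain. In the second column MTRNR2L8 exceeded MT-ND4L, with 7423 against 6536 FPKM. WDR74, which overlaps a copy of the U2 spliceosomal RNA, had 3807 ± 84.3 FPKM, and LINC00273 had 4676 ± 967 FPKM. Among the 20 were also KRT8 and KRT18, the keratins of simple epithelia, with 1143 ± 38.7 and 1102 ± 31.5 FPKM. HIST1H2AH and HIST1H3G, which encode core histones, had 1205 ± 161 and 1032 ± 167 FPKM, and RPL32, a ribosomal protein gene, had 1015 ± 145 FPKM. SPINK9 had 1029 ± 255 FPKM, and IER3, an early response gene, 949 ± 160 FPKM. The transcripts CTD-2117L12.1, AL590867.1, AL158821.1 and AL139147.1 had 1349 ± 18.3, 1296 ± 159, 1234 ± 11.4 and 1037 ± 0.354 FPKM. The 20 highest genes of each column held 17.2% of the summed FPKM in the first and 13.9% in the second.

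Luminal breast genes were listed in full and high, whereas markers of other cell types were mostly absent from the table. All 16 luminal markers were listed, against 6 of 16 basal or mesenchymal markers, 1 of 12 blood cell markers and 1 of 12 fibroblast or endothelial markers. The luminal markers had a median of 63.7 ± 9.83 FPKM (SD of the 2 column medians, n = 2), and 13 of them lay above the median of the table. After KRT8 and KRT18 the highest were XBP1, a secretory pathway transcription factor, with 423 ± 78.0 FPKM, and GATA3, a luminal lineage factor, with 271 ± 19.1 FPKM. KRT19 had 168 ± 6.86 FPKM, and FOXA1, a pioneer factor for the estrogen receptor, had 110 ± 3.86 FPKM. CDH1, which encodes E-cadherin, had 70.3 ± 10.3 FPKM, MLPH 57.1 ± 9.36 FPKM and SPDEF 50.8 ± 17.9 FPKM. EPCAM had 31.8 ± 7.32 FPKM and AGR2 25.9 ± 3.77 FPKM. ESR1, the gene of the estrogen receptor itself, was close to the table median with 17.5 ± 3.14 FPKM. MUC1 had 15.03 ± 0.370 FPKM, PGR, the progesterone receptor gene, 12.0 ± 0.670 FPKM, and TBX3 the lowest luminal value of 3.08 ± 0.409 FPKM.

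The 6 listed basal or mesenchymal markers had a median of 8.91 ± 0.679 FPKM, and the luminal median was 7.53-fold higher in the first column and 6.73-fold higher in the second. CAV2, a caveolin, had 16.9 ± 1.24 FPKM, FOXC1 10.5 ± 0.897 FPKM and CD44 10.2 ± 0.970 FPKM. AXL had 8.12 ± 1.09 FPKM, FN1, the fibronectin gene, 7.04 ± 0.262 FPKM, and SNAI2 5.92 ± 2.56 FPKM. KRT5, KRT14, TP63, EGFR, CAV1, VIM and ZEB1 were among the 10 that were not listed. The listed blood marker was CORO1A, an actin-binding protein gene, with 36.2 ± 9.55 FPKM, and the listed stromal marker was COL3A1, a collagen gene, with 3.55 ± 0.0636 FPKM. The share of luminal markers listed exceeded that of the basal or mesenchymal markers by two-sided Fisher's exact test (p = 0.000248, Benjamini-Hochberg adjusted p = 0.000248 over 3 comparisons). It also exceeded those of the blood and of the fibroblast or endothelial markers (exact p = 5.59e-07 and adjusted p = 8.38e-07 for each). Genes are not independent replicates, and the rule that admitted a gene to the table is not given in the sources used here.

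**Figure D1:**
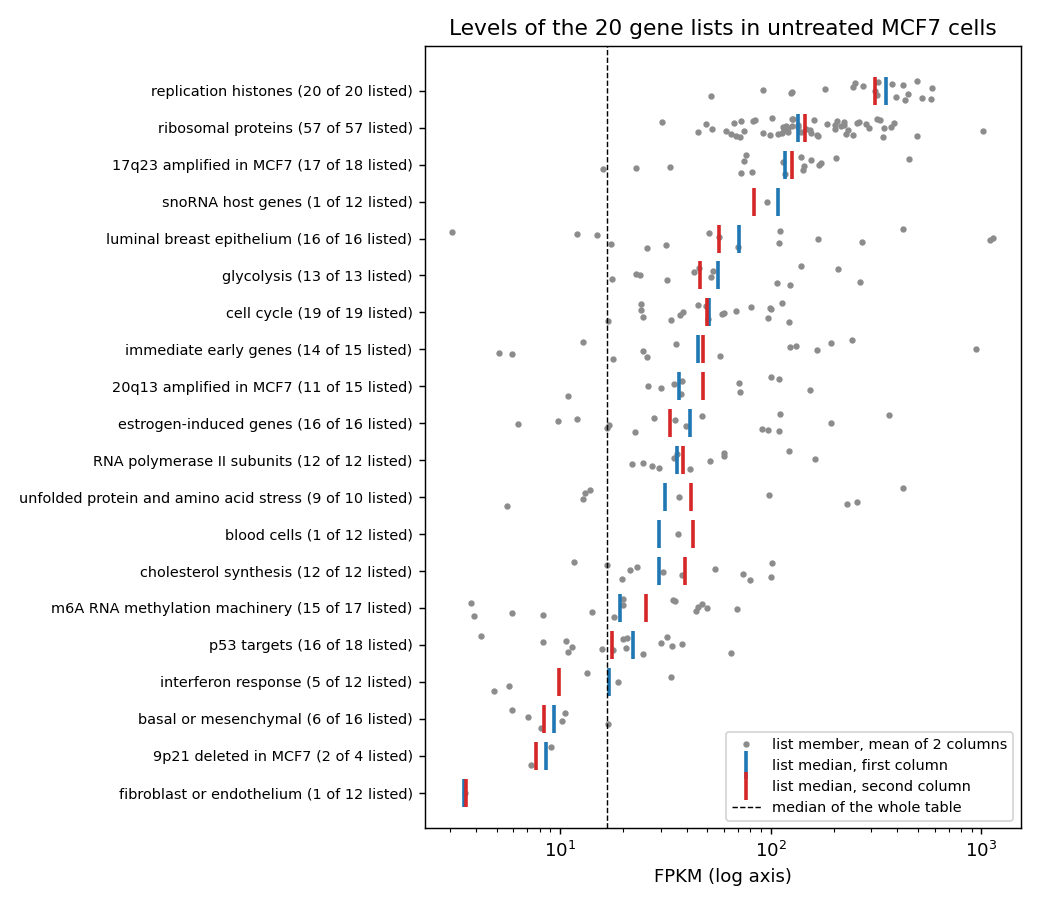
Levels of the 20 gene lists, with FPKM on a logarithmic horizontal axis and 1 list per line. Grey points are the listed members (mean of 2 columns, vertical offsets only separate them), blue and red bars are the list medians of the first and second column, and the dashed line is the table median. Histone, ribosomal protein and 17q23 lists lie highest, with medians of 332, 140 and 122 FPKM, and the 6 listed basal or mesenchymal markers have a median of 8.91 FPKM.

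Of the 16 lists with at least 3 listed members, 12 had a median level above the central 95% of 10000 random lists of their size, and 0 lay below it. The estrogen-induced genes were among the 12, with all 16 members listed, a median of 37.5 ± 5.75 FPKM and percentile 99.7. STC2, a secreted glycoprotein gene, was the highest of them with 366 ± 43.9 FPKM. MYC had 194 ± 23.02 FPKM, TFF1, the trefoil peptide gene used as an indicator of receptor activity, 111 ± 3.55 FPKM, and CA12, a carbonic anhydrase gene, 110 ± 7.48 FPKM. MYB was the lowest with 6.30 ± 0.155 FPKM. The immediate early genes, 14 of 15 listed, had a median of 46.6 ± 1.86 FPKM at percentile 99.9. Within them IER3 was followed by ZFP36, an mRNA decay factor, with 244 ± 96.1 FPKM, MYC, and IER2 with 165 ± 20.7 FPKM. FOS, the canonical member, had only 5.13 ± 0.745 FPKM.

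Histone, ribosomal protein and proliferation genes stood high throughout. All 20 replication-dependent histone genes lay above the table median and 19 of them in its top 10%, with a median of 332 ± 29.5 FPKM. HIST1H3B had 583 ± 57.6 FPKM, HIST1H1C 575 ± 39.0, HIST1H1D 524 ± 105 and HIST2H2BE 498 ± 71.5 FPKM, and the lowest, HIST1H2AC, had 51.9 ± 1.25 FPKM. Several genes of the same histone type share near-identical coding sequences, so single members can be uncertain. All 57 ribosomal protein genes lay above the table median, 53 of them in the top 10%, with a median of 140 ± 7.90 FPKM. After RPL32, the highest were RPL12 with 498 ± 52.1, RPS2 with 386 ± 4.38 and RPLP0 with 375 ± 3.10 FPKM, and RPS24 was lowest with 30.5 ± 6.00 FPKM. All 19 cell cycle genes lay above the table median, with a median of 50.3 ± 1.01 FPKM. AURKA, a mitotic kinase, had 122 ± 16.5 FPKM, TYMS, thymidylate synthase, 113 ± 10.3, MCM7, a helicase subunit, 101 ± 13.9, and MKI67 99.7 ± 15.5 FPKM, whereas BUB1 had 16.9 ± 3.06 FPKM. All 3 lists were at percentile 100. Their random lists were not matched on gene length, so a part of length in these levels was not tested.

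Metabolic lists were also above the table. All 13 glycolysis genes exceeded the table median, with a median of 51.0 ± 6.97 FPKM at percentile 99.98. GAPDH had 266 ± 56.3 FPKM, PKM 208 ± 5.22, TPI1 140 ± 8.15 and ALDOA 124 ± 19.6 FPKM, and HK2, a hexokinase gene, had 17.6 ± 0.166 FPKM. All 12 genes of cholesterol synthesis were listed, 11 above the table median, with a median of 34.4 ± 6.91 FPKM. SQLE, squalene epoxidase, had 101 ± 0.0417 FPKM, FDPS 100.03 ± 7.87, DHCR7 79.6 ± 12.5 and HMGCS1 73.6 ± 7.26 FPKM, and SREBF2, the regulator of the pathway, 11.7 ± 0.622 FPKM. The list was at percentile 98.8 over both columns, and at 96.5 in the first column alone, inside the central 95% of random lists. The unfolded protein and amino acid stress genes, 9 of 10 listed, were split, with 5 above the table median. XBP1, DDIT3 (258 ± 117 FPKM), ATF4 (230 ± 7.69 FPKM) and HSPA5 (98.0 ± 3.55 FPKM) were high and ASNS, asparagine synthetase, low with 5.60 ± 0.318 FPKM. This list was at percentile 97.68, at 95.4 in the first column alone, and at 78.1 without XBP1, which the luminal list also holds.

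The listed p53 targets and the listed interferon genes did not stand apart from random lists. Of 18 p53 targets 16 were listed, with a median of 20.0 ± 3.36 FPKM at percentile 74.8. BAX had 65.0 ± 2.26 FPKM, MDM2 38.1 ± 1.22, GDF15 33.9 ± 1.63 and XPC 32.1 ± 1.45 FPKM, and ZMAT3 4.23 ± 0.282 FPKM. Of 12 interferon response genes 5 were listed, with a median of 13.4 ± 5.06 FPKM at percentile 30.5, which was 51.3 in the first column alone and 14.9 in the second. IRF9 had 33.7 ± 3.19 FPKM, IRF7 18.9 ± 0.351, STAT1 13.4 ± 5.06 and IFIT3 5.70 ± 2.67 FPKM, and DDX58, an RNA sensor, 4.88 ± 0.445 FPKM. IFIT1, ISG15, MX1 and OAS1 were among those not listed, and the interferon percentile covers only the listed genes. The 6 listed basal or mesenchymal markers were at percentile 7.42. When only genes above the lower quartile of the table were used, 3 of these markers were left, at percentile 1.65. Of 12 snoRNA host genes only SNHG16 was listed, with 96.1 ± 17.6 FPKM. Since 98.9% of the listed genes with an annotated type were protein-coding, this absence is no measure of transcription.

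All 12 subunits of RNA polymerase II lay above the table median, with a median of 37.1 ± 1.81 FPKM at percentile 99.7. POLR2G had 162 ± 63.2 FPKM, POLR2L 122 ± 2.43 and POLR2I 60.4 ± 10.6 FPKM, and POLR2D was lowest with 22.0 ± 3.44 FPKM. POLR2K had a mean of 59.9 ± 35.4 FPKM, and its columns were 2.44-fold apart. The machinery of N6-methyladenosine (m6A), a mark placed on RNA during transcription, was less uniform. Of 17 genes 15 were listed, with a median of 22.4 ± 4.39 FPKM at percentile 71.4. METTL3, the catalytic subunit of the methyltransferase, was highest with 69.3 ± 8.66 FPKM, followed by RBM15 with 49.7 ± 4.52, the nuclear reader YTHDC1 with 47.3 ± 1.78 and RBM15B with 45.0 ± 1.89 FPKM. YTHDC2 was lowest with 3.78 ± 0.276 FPKM.

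Genes of the 17q23 region, which is amplified in MCF7, formed the third highest list. Of 18 genes 17 were listed, 16 lay above the table median and 14 in its top 10%, with a median of 122 ± 7.26 FPKM at percentile 100. VMP1, an autophagy gene, had 454 ± 57.4 FPKM, TRIM37, a ubiquitin ligase gene, 204 ± 18.2, PTRH2 174 ± 10.7 and PPM1E, a phosphatase gene, 170 ± 0.923 FPKM, and DHX40 was lowest with 16.04 ± 0.738 FPKM. Of 15 genes from 20q13, a further amplified region, 11 were listed, with a median of 42.1 ± 7.87 FPKM at percentile 98.7. NCOA3, a receptor coactivator gene, had 154 ± 8.11 FPKM, SULF2 109 ± 11.1, ZNF217 100.5 ± 19.0 and BCAS4 71.5 ± 21.5 FPKM, and ARFGEF2 10.9 ± 1.57 FPKM. The 20q13 list was at percentile 96.05, within the central 95%, when only genes above the lower quartile of the table were used. From 9p21, fixed beforehand as a region deleted in MCF7, CDKN2A and MTAP were not listed. CDKN2B was listed with 7.30 ± 1.82 FPKM and DMRTA1 with 9.03 ± 0.564 FPKM, so the values do not show a loss of every gene on this list. The labels give no copy number, and FPKM does not separate the number of gene copies from transcription per copy.

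**Figure D2:**
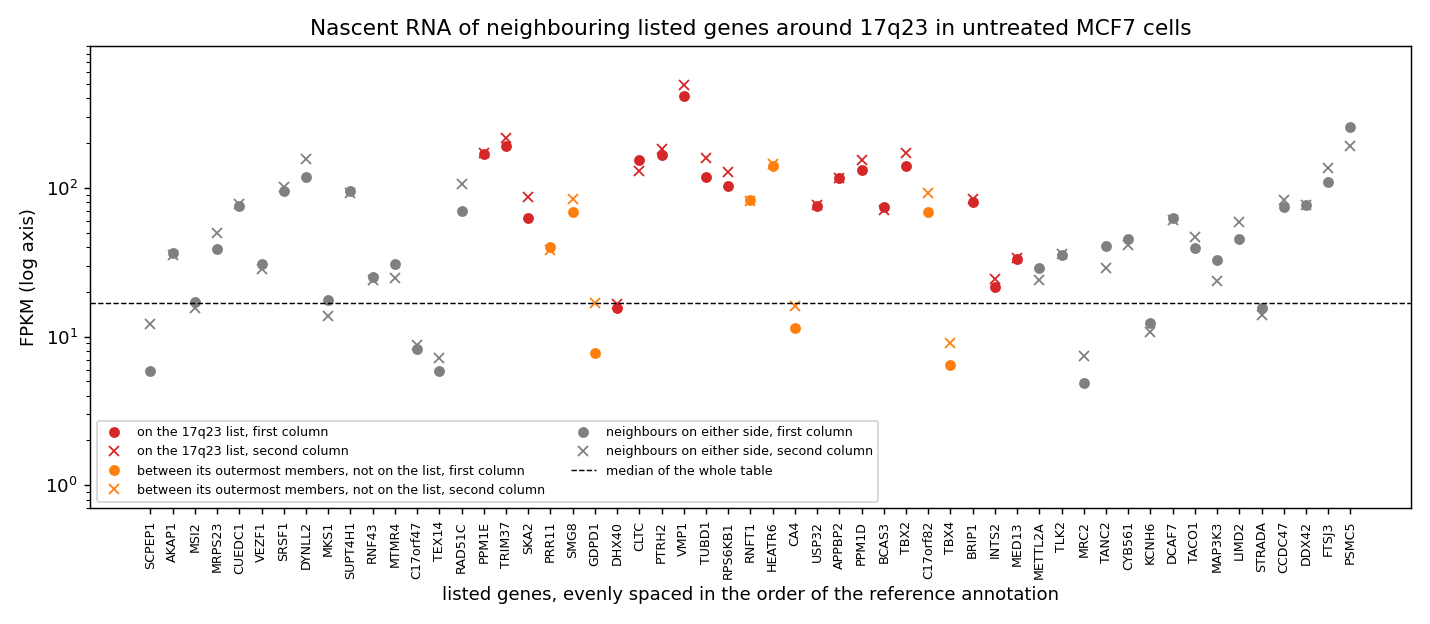
Neighbouring listed genes around 17q23, evenly spaced in the order of the reference annotation, with FPKM on a logarithmic vertical axis. Circles are the first and crosses the second column, red marks genes on the 17q23 list, orange the 8 listed genes between its outermost members, grey 15 neighbours on each side, and the dashed line the table median. Among the list genes VMP1 is highest, with a mean of 454 FPKM over the columns, and 16 of 17 lie above the table median.

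The 2 columns ranked genes alike, and few genes differed between them by more than 2-fold. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.968 and Spearman's rho 0.961. The median gene differed 1.16-fold, and 85 of 11410 genes (0.745%) differed by more than 2-fold on that scale, 58 higher in the second column and 27 lower. In simulated columns with no changed gene and normal noise of 1 spread for all genes, 34 genes did. The noise of the real columns need not have that form, so 85 against 34 does not count changed genes. With a pseudocount of 0.1 the number in the real columns was 143, with 10 it was 20, and at a limit of 1.5-fold it was 959. Among genes above the median level, the largest ratios of second to first column belonged to MPHOSPH6, an RNA processing factor, with 9.87 and 32.4 FPKM. AKAP3 had 11.5 and 34.9 FPKM, ENDOG, a mitochondrial nuclease gene, 12.5 and 36.3, ESF1, a nucleolar factor gene, 30.6 and 88.5, and SGOL1, a protector of centromere cohesion, 17.6 and 49.0 FPKM. The smallest ratios belonged to CTC-203F4.1 with 42.0 and 13.4 FPKM, ZNF385A with 35.5 and 13.97, GOSR2, a Golgi transport gene, with 28.2 and 11.2, ZDHHC7 with 30.2 and 12.5, and ARPC4, an actin nucleation subunit, with 39.4 and 16.6 FPKM. With 1 column against 1 there is no test of any single gene.

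Of the 16 lists, 2 had a median difference between the columns outside the central 95% of random lists matched on level, where 0.8 would be met by chance. The estrogen-induced genes had a median log2 ratio of second to first column of -0.21 at percentile 0.39, with 13 of 16 members lower in the second. The 20q13 genes had a median log2 ratio of -0.21 at percentile 1.38, with 7 of 11 lower. Their column medians, 36.5 and 47.7 FPKM, went the other way, so the 20q13 difference has no single direction. Both values describe these 2 columns and no condition.

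**Figure D3:**
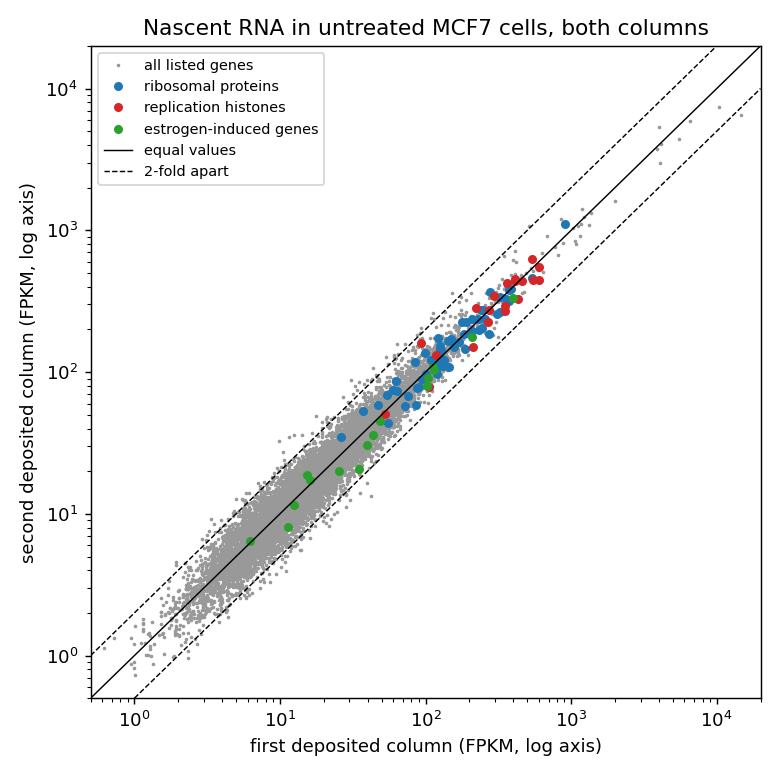
First against second column for the 11410 listed transcripts, both in FPKM on logarithmic axes. Grey points are all genes, blue ribosomal protein, red replication histone and green estrogen-induced genes, the solid line marks equal values and the dashed lines 2-fold differences. Most points lie between the dashed lines, and 13 of 16 estrogen-induced genes lie below the line of equal values.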

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

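Alternatives on symbols shared by lists, on runs of neighbours, and on the genes over 2-fold among those above the table median were chosen after seeing the data. The difference in listing between luminal markers and each other cell type stayed past the threshold in 6 of 6 alternatives by level; leaving out a column gives no other listing, because 1 table holds both. Of 96 alternatives for the list levels, 90 stayed on the same side of the central 95% of random lists. With only genes above the lower quartile, the cholesterol synthesis list was at percentile 93.53 and the 20q13 list at 96.05, against fewer genes. The basal or mesenchymal list, with 3 members left, was at 1.65 there. Leaving out 1 column gave 96.52 to 99.56 for cholesterol synthesis and 95.4 to 98.88 for the unfolded protein and amino acid stress list, with the lower value from the first column in each. Without symbols that occur in another list, the latter was at 78.07. For the differences between the columns, 32 of 32 alternatives stayed on the same side, leaving out centring, which cannot move a percentile. The 17q23 run was the second highest in 3 of 3 alternatives. The 85 genes over 2-fold became 143 with a pseudocount of 0.1, 20 with 10, 959 at a 1.5-fold limit and 52 among genes above the median, where fewer genes were counted. For named genes, leaving out 1 column moved the value by over 1.5 times in 15 of 240 alternatives, mostly the genes named for their ratio. Random lists matched on gene length, and the alternatives for gene length and chromosome windows, were not run because no lengths or positions of the build were used. No paired analysis was possible because there was 1 group. The absolute depth is unknown, so no counting error can be given for any gene. Without a pseudocount, the SD of the log2 ratio of the columns was 0.42 in the lowest 10% of genes by level and 0.34 in the highest. A pseudocount of 1 shrinks the low end, to 0.32 against 0.33.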

Other observations

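Tests on 17q23 and on the estrogen-induced list were chosen after the result was seen, as were the test without the 4 highest members for 20q13, the symbol families and the runs of neighbours. Grouped by the letters before the first digit of the symbol, 115 families had at least 10 listed genes. Of these, 15 had a median above the central 95% of random lists and 19 below it, where 2.875 on each side would be met by chance. Beside histones and ribosomal proteins, the splicing factors of the SRSF family stood high, with a median of 70.4 ± 2.72 FPKM over 11 genes (SD of the 2 column medians, n = 2). The mitochondrial ribosomal proteins of the small subunit (MRPS, 24 genes) had 40.9 ± 0.759 FPKM, and those of the large subunit (MRPL, 43 genes) 34.3 ± 3.17 FPKM. The 10 NDUFB genes, which encode subunits of complex I, had 41.1 ± 8.28 FPKM, and the 17 genes with the letters COX, subunits and assembly factors of cytochrome oxidase among them, had 36.8 ± 7.21 FPKM. RNA-binding RBM genes (33) had 30.3 ± 1.98 FPKM and DDX helicases (34) 34.0 ± 2.98 FPKM. At the low end, 10 genes with the letters COL, mostly collagens, had 5.38 ± 0.616 FPKM, and 0 of them exceeded the table median. The EXOC genes of the exocyst (10 genes) had 7.18 ± 0.0725 FPKM, phosphodiesterases (PDE, 12 genes) 7.20 ± 0.491, DENND regulators of Rab proteins (11 genes) 7.34 ± 0.820 and the ARHGEF activators of Rho proteins (21 genes) 8.21 ± 1.21 FPKM. The 416 ZNF genes lay near the middle, with 15.4 ± 0.288 FPKM at percentile 9.30. Gene lengths were not used, so a part of length in this order of families was not tested.

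Runs were ranked by their median log2(FPKM + 1). Along the reference order of genes, the highest run of 15 neighbours was the histone cluster from HIST1H4B to HIST1H1D, with a median of 306 ± 12.3 FPKM. The second highest ran from GDPD1 to TBX2 within 17q23, with 122 ± 7.26 FPKM, and the fifth, from MRPS23 to SKA2 with 70.5 ± 10.7 FPKM, ended before PRR11 and SMG8, the listed genes that precede GDPD1. A run from PTPN22 to ATP1A1OS, which holds NRAS and CSDE1, was among the 10 highest, with 67.9 ± 3.91 FPKM. The lowest run, from HARS2 to PCDHGA3, held the clustered protocadherin genes, with 3.64 ± 0.454 FPKM. Some protocadherin transcripts overlap one another, so single values of those are uncertain. The median over 728 runs that do not overlap was 16.2 FPKM.

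The 17q23 list lay above random lists. Only 1 of 725 runs of neighbouring genes elsewhere reached its median, which argues against an ordinary stretch of active neighbours. Those runs hold every listed neighbour, whereas the list leaves out 8 listed genes of its span. The run from GDPD1 to TBX2, which leaves out none between its ends, had a median of 122 ± 7.26 FPKM, but was found by its height. Without its 4 highest members the 17q23 list was at percentile 100 of random lists that lost theirs, so a few high members do not account for its level. A candidate explanation that stays open is the gain of this region in MCF7, since the 8 listed genes between its outermost members that are not on the list were at percentile 99.84, with a median of 57.6 FPKM and 5 of 8 above the table median. The 15 listed neighbours before the span had a median of 29.7 ± 1.46 FPKM and the 15 after it 40.96 ± 0.544 FPKM, with 10 and 12 above the table median, so the values do not set where the high stretch ends, and copy number was not measured.

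The 20q13 list also lay above random lists, less far. Its 4 highest members do not account for it, since without them it was at percentile 99.96 of random lists treated alike. The 25 other listed genes in its span were at percentile 100, with PARD6B at 170 ± 2.02 FPKM and BMP7 at 95.5 ± 2.16 FPKM. AURKA, the highest gene of the cell cycle list, also lies in this span, with 122 ± 16.5 FPKM. A regional gain may therefore contribute, but 46 of 725 runs elsewhere (6.34%) reached the list's median, so an ordinary stretch of active neighbours stays open as well.

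The estrogen-induced list was lower in the second column, with 13 of 16 members lower. Among these the fall was smallest for TFF1, from 113 to 108 FPKM, and largest for RARA, from 35.1 to 20.7 FPKM. Of the 16 lists, 13 had a difference below percentile 50. Against random lists drawn from 242 members of the other lists, not matched on level, the estrogen-induced list was at percentile 1.58. The list was picked because it was extreme among the 16, so this percentile cannot decide whether the shared lean accounts for it. Among 10000 sets of 16 percentiles drawn evenly, 12.02% held one as extreme as that of this list, so chance among the lists examined may account for it, if the percentiles are evenly spread, which the lean leaves in doubt. Level does not, because the random lists were matched on it, and no biological explanation was tested since both columns are of untreated cells.

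The 6 MTRNR2L genes and the 4 genes with MT symbols were lower in the second column, and together they held 11.03% of the summed FPKM in the first column and 7.67% in the second. Much of this difference lay in MT-ND4L, and without it the shares were 7.30% and 6.00%. MT-CO1 had nearly equal values of 4163 and 4057 FPKM. The tally went by the letters of the symbol, so mitochondrial genes under other names are missing from it and the shares can be too low. J01415.25, among the 20 highest genes and not in this tally, had 4056 and 2968 FPKM.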
